A study of Mus musculus with 48 samples.

How the data were processed

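Total RNA from the livers of mice was labelled with Cy3 and read on 48 one-colour Agilent arrays. Per the labels, the mice were 14 weeks old, male or female, wild type (LWT) or with Ppara deleted in hepatocytes (LKO), and fed or fasted for 24 h. Each of the 8 groups had 6 arrays. Which part of Ppara was deleted, how it was deleted and whether each sample came from 1 mouse are not given in the sources used here. Per the file headers, the arrays sat on 6 slides of 8, with 1 array of every group on each slide, and per the labels they were washed in 4 batches, each holding whole slides.

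The scanned intensity of every spot was extracted with Agilent Feature Extraction 10.10.1.1, per the file headers and the submitters' processing notes. The processed signal is an intensity on the linear scale with background subtracted and surrogate values for dim spots, per the file headers, and it carries no scaling between arrays. The mean and median spot signals are raw intensities, per the file headers. The authors also deposited a table of log2 values for 32131 probes and 48 arrays. Every column of that deposited table has a median of 7.859 on the log2 scale and the same distribution. Its lowest correlation with an array's own log2 median signal was 0.9956, and with the scaled processed signal 0.9847. The notes name limma without a version, and neither the steps behind the deposited log2 table nor the filter that left 32131 of 56605 probes is stated, so the table served only as an alternative.

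For the main results, the log2 processed signal of each array was set relative to the 75th percentile of its 56605 non-control probes. The 3671 control spots and 4646 spots marked as outliers by the extraction software were left out, repeated spots of a probe were averaged, and 0 of the non-control spots were saturated. A probe was kept if the software marked it as well above background on at least 5 of 6 arrays of at least 1 group, which left 32386 probes. Each gene was represented by its kept probe with the highest mean over all 48 arrays, giving 21282 genes. The 75th percentile of intensity per array and the percent of probes well above background measure the depth of each array.

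Probes were named through a table of RefSeq genes for GRCm38.p6, used for names only. It matched 32994 probes by accession, 10224 by symbol and 520 by an older symbol, while 12867 kept the name in the file, and 2055 names changed. The probe positions in the file headers refer to mm9.

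A linear model with 8 group means was fitted to all 48 arrays (limma 3.58.1, R 4.3.3, version 1.17.8 of data.table), with moderated t-tests on 40 residual degrees of freedom and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at adjusted p under 0.05. Comparisons covered fasting within each genotype and sex, genotype within each sex and feeding state, sex within each genotype and feeding state, and the differences between these effects. For a gene well above background on no array of the dimmer group, that group was set to at least the dimmest signal marked as well above background on its own arrays, which gives a lower bound of the fold. The overlap of genes raised by fasting and lower in fasted LKO livers was set against independent lists, and the covariance of both effects against 100 simulations from the residuals.

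Genes named in the text follow a rule. In each comparison it takes the 8 largest rises and the 8 largest falls among called genes, with no overlap between the arrays where 2 groups are compared and with predicted features left out. From every list it takes up to 4 called members with the lowest adjusted p, and members that were not called may be given as values. Ppara, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty always belong to it. Some genes that the rule takes are not reported here.

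The 31 lists held 504 genes, of which 498 had a probe. They cover mitochondrial fatty acid oxidation, ketogenesis, peroxisomal fatty acid oxidation, microsomal omega-oxidation (Cyp4a), lipid droplets, other known PPARα targets, fatty acid synthesis, cholesterol synthesis and uptake, gluconeogenesis, amino acid catabolism with the urea cycle, and bile acid synthesis and transport. Further lists cover the amino acid response (Atf4), endoplasmic reticulum chaperones, the circadian clock, insulin and glucocorticoid responsive genes, the growth hormone axis, the acute phase, antioxidant (Nrf2) genes, xenobiotic metabolism (CAR and PXR), male-biased and female-biased liver genes, the cell cycle and sex chromosome genes. Marker lists stood for hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells and fibroblasts, cholangiocytes, and blood and neighbouring tissues. They were written from general knowledge of liver biology. Each list was tested with camera in limma, with its correlation estimated from the residuals and adjustment over the lists of a comparison. The preset correlation of 0.01 and fry were run as alternatives.

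The fits were tested on simulated data for 21282 genes, with 50 changed genes per fold size. Each value was drawn independently around the gene's mean over all arrays, with the gene's spread within groups. Alternatives for the processing were quantile normalization, normexp background correction with an offset of 50, the uncorrected median signal with quantile normalization, the deposited values, no filter, a filter on all 48 arrays, the mean of a gene's probes, a fit of only the groups compared, slide, wash batch and replicate number as blocks, each slide left out, adjusted p under 0.01, a 2-fold minimum, each Ppara probe alone and, chosen after seeing the data, 4 single arrays left out in turn. For other splits, the arrays of each comparison of 2 groups, and of each overlap, were regrouped at random into groups of the same sizes. For differences between effects, the residuals of a model without the difference were permuted over the arrays and added back to its fitted values. Each had 100 splits with the real one included. Correlations over arrays used deviations from group means and 100000 permutations within sex, and all permutations for each sex alone. All random steps used a fixed random seed of 1. No array was left out of the main results.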

Results

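Liver RNA of 14-week-old mice was measured on 48 single-colour Agilent arrays. Wild-type livers (LWT) and livers whose hepatocytes lacked Ppara (LKO) came from males and females, fed freely or fasted for 24 h, with 6 arrays in each of 8 groups. The arrays sat on 6 slides, and each slide held 1 array of every group. The 75th percentile of signal ran from 334.4 to 618.1 per array, and 43.15 to 60.93% of probes were well above background. After filtering, 21282 genes were tested. The labels list separate samples per group and do not state that each is 1 mouse, so the p-values measure the spread between these samples, and 6 arrays per group limit the precision of every value.

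The first principal component held 30.7% of the variance and separated the sexes, and the second held 20.4% and separated fed from fasted livers. Component 3 held 10.2% and set LWT apart from LKO livers. Within a group, the lowest mean correlation of an array with the rest of its group was 0.9852. The silencing RNA of the inactive X chromosome and the Y-linked genes placed every group with its labelled sex. In fed LWT livers Ddx3y was at least 15.6-fold lower in females and Eif2s3y at least 162-fold lower, while Xist was at least 18.1-fold higher (adjusted p = 2.96e-36, 4.72e-35 and 2.49e-16). The probe kept for Kdm5d, also Y-linked, did not separate them (-0.18 ± 0.21, adjusted p = 0.576). Here and below, "at least" marks a gene that was well above background on no array of the dimmer group: that group was set to the dimmest signal accepted on its own arrays, so the fold is a lower bound. Where only some arrays of the dimmer group passed, the printed size rests partly on dim signal.

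**Figure D1:**
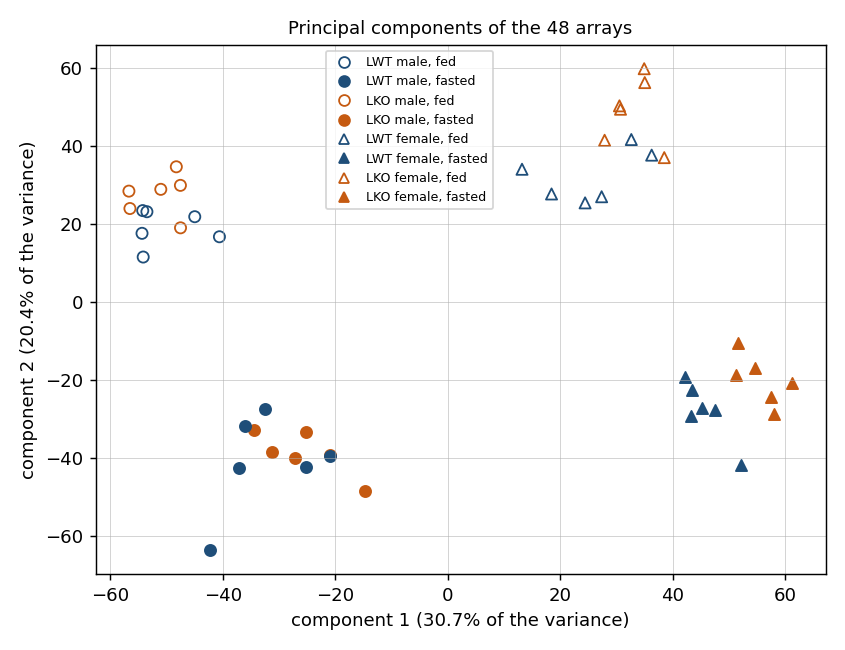
Principal components of 48 arrays (log2 signal), from those of the 21282 genes that had a value on every array. Axes give the first and second component scores. Colours mark genotype, marker shapes sex, and open or filled markers fed or fasted livers. Component 1 (30.7% of variance) separates males from females, and component 2 (20.4%) separates fed from fasted livers.

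Ppara itself was lower in LKO livers in all 4 pairs of groups. Values are log2 differences ± SE with p-values adjusted over all genes by limma. The brighter of its probes fell by -0.70 ± 0.11 in fed males (adjusted p = 1.34e-05), -0.96 ± 0.11 in fed females (6.59e-09), -0.99 ± 0.11 in fasted males (1.07e-09) and -1.50 ± 0.11 in fasted females (2.95e-15). These values leave 61.5%, 51.3%, 50.3% and 35.2% of the LWT signal, and the dimmer probe left 54.7%, 48.2%, 42.1% and 32.1%. Ppara was lower in LKO on 6 of 6 slides in every pair. In LWT livers fasting raised Ppara by 0.64 ± 0.11 in males (mean 5.77 ± 0.12 SD fed, 6.41 ± 0.21 fasted) and by 0.44 ± 0.11 in females (adjusted p = 6.41e-06 and 0.00111). In LKO livers it rose in males (0.35 ± 0.11, adjusted p = 0.00712) and was not called in females (-0.11 ± 0.11, adjusted p = 0.45), and the difference between the sexes was not tested. The signal that was left does not measure how many hepatocytes kept the gene: the labels do not say which part was deleted, the probes may lie outside it, and other liver cells contribute RNA.

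**Figure D2:**
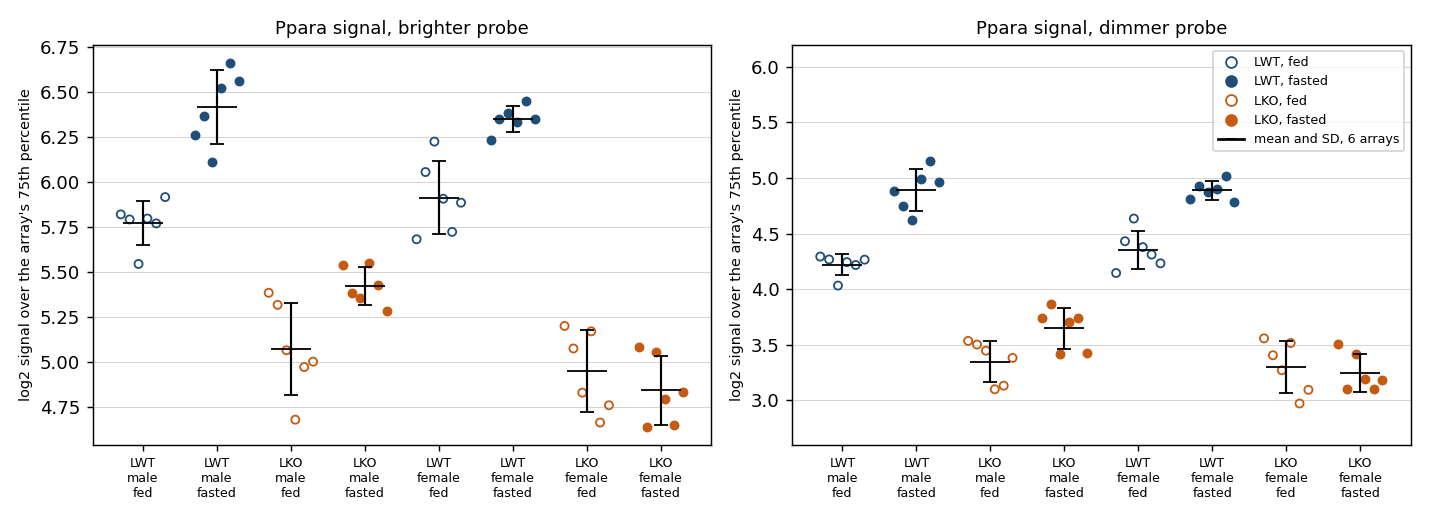
Ppara log2 signal of both probes on each of 48 arrays (points) by group, 6 arrays per group, with the vertical axis in log2 units relative to the array's 75th percentile. The brighter probe averages 5.77 in fed LWT males and 5.07 in fed LKO males, and 6.35 in fasted LWT females and 4.84 in fasted LKO females.

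Fasting changed 6404 genes in LWT males (3255 rose, 3149 fell), 7017 in LWT females (3707 and 3310), 7818 in LKO males (3806 and 4012) and 8830 in LKO females (3960 and 4870). Of these, 995, 965, 1217 and 1339 changed at least 2-fold. Both LWT sexes shared 4205 genes changed in the same direction (2260 rose and 1945 fell, with 567 and 489.8 expected of independent lists), and 18 changed in opposite directions. Across all genes the changes of males and females correlated at r = 0.762 in LWT and 0.776 in LKO. Which direction held more genes rested on the scaling in LWT livers: falling genes were 49.2% of the calls in males and 47.2% in females, but 54.2% and 53.3% with quantile normalization.

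**Figure D3:**
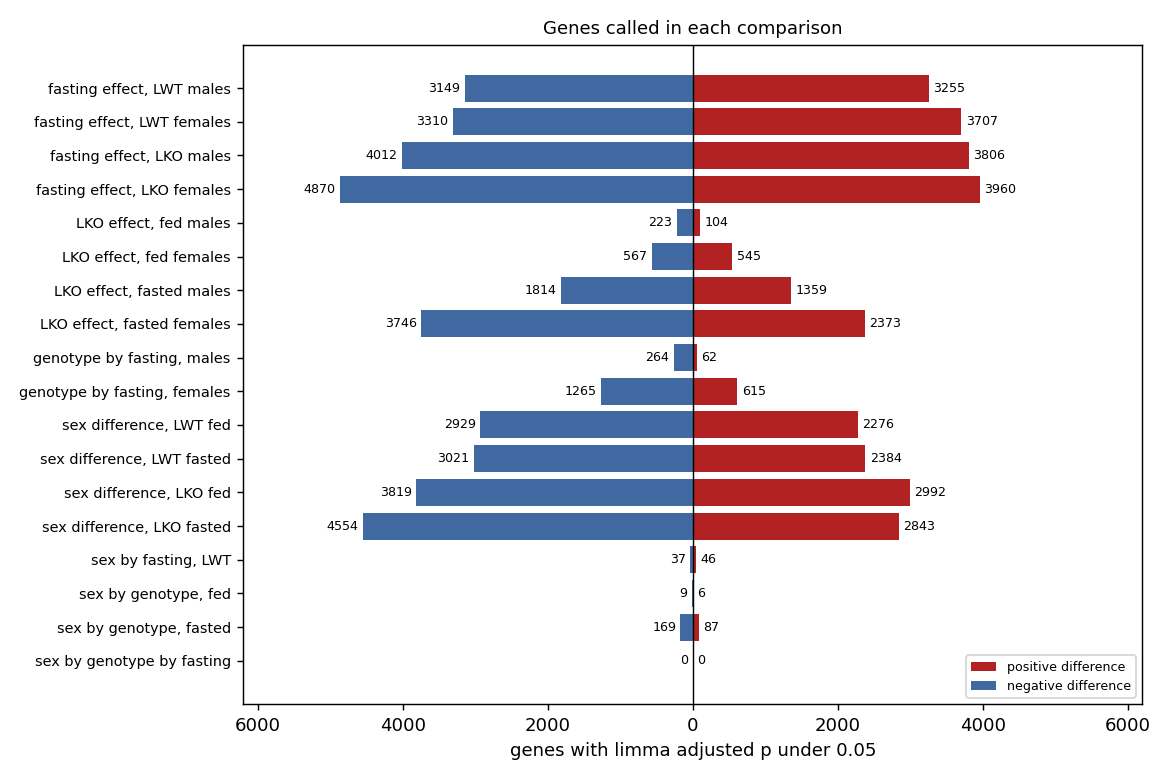
Number of genes called at adjusted p under 0.05 (horizontal axis, higher and lower drawn to either side) for each comparison, 6 arrays per group. Fasting called 6404 to 8830 genes, and loss of Ppara called 327 in fed males and 6119 in fasted females.

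Fasted LWT livers raised the genes that burn fat. All 19 genes of mitochondrial fatty acid oxidation rose in both sexes (19 also when adjusted over the list alone, camera adjusted p = 0.00407 in males and camera adjusted p = 0.00398 in females). They included the beta subunit of the trifunctional protein, Hadhb (0.99 ± 0.061, adjusted p = 1.62e-15) in males, and the medium-chain dehydrogenase, Acadm (1.09 ± 0.075, adjusted p = 1.55e-14) in females. In the peroxisomal list 13 rose, 1 fell and 1 was not called (14 and 1 over the list alone, camera adjusted p = 0.00966) in males. In females 13 rose, 1 fell and 1 was not called (unchanged over the list alone, camera adjusted p = 0.0136). Its bifunctional enzyme Ehhadh rose by 2.19 ± 0.16 and 1.81 ± 0.16. Of the ketogenic genes, 4 rose, 1 fell and 1 was not called (unchanged over the list alone, camera adjusted p = 0.252 with an estimated correlation) in males. In females 4 rose, 0 fell and 2 were not called (5 and 0 over the list alone, camera adjusted p = 0.261 with an estimated correlation). Omega-oxidation genes were led by Cyp4a14 (6.19 ± 0.77, adjusted p = 2.38e-08), Cyp4a10 (4.51 ± 0.53, adjusted p = 7.57e-09) and Cyp4a31 (3.88 ± 0.50, adjusted p = 4.98e-08) in males. The size for Cyp4a14 rests on an uneven fed group, with replicates 3 and 5 at 0.04 and -1.26 and the other 4 arrays between -5.60 and -4.66. In that list, 6 rose, 1 fell and 2 were not called (unchanged over the list alone, camera adjusted p = 0.113 with an estimated correlation) in males. In females 4 rose, 1 fell and 4 were not called (6 and 1 over the list alone, camera adjusted p = 0.413).

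Other known PPARα targets rose with them. In LWT males 11 rose, 0 fell and 10 were not called (12 and 0 over the list alone, camera adjusted p = 0.00407), and in LWT females 17 rose, 0 fell and 4 were not called (unchanged over the list alone, camera adjusted p = 0.000122). The carnitine transporter Slc22a5 rose by 2.09 ± 0.13 and 2.54 ± 0.13, and the retinol saturase Retsat by 2.02 ± 0.16 and 2.12 ± 0.16. The thioesterases Acot1 and Acot2 rose by 2.82 ± 0.28 and 2.50 ± 0.24 in males and by 3.38 ± 0.28 and 3.41 ± 0.24 in females. In females the hormone gene Fgf21 rose by 4.35 ± 0.61 and the kinase gene Pdk4, which spares pyruvate, by 3.73 ± 0.32 (adjusted p = 2.85e-07 and 3.73e-12). Both genes also rose with fasting on 6 of 6 slides in LWT males. Lipid droplet genes followed: 9 rose, 1 fell and 5 were not called (unchanged over the list alone, camera adjusted p = 0.144 with an estimated correlation) in males. In females 10 rose, 0 fell and 5 were not called (unchanged over the list alone, camera adjusted p = 0.00732). The droplet coat gene Plin4 rose by 2.62 ± 0.34 and 4.56 ± 0.34, and the lipase Pnpla2 by 1.34 ± 0.11 and 1.48 ± 0.11.

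Lipid building genes fell in the same livers. Of the genes of fatty acid synthesis, 0 rose, 16 fell and 5 were not called (0 and 19 over the list alone, camera adjusted p = 0.00997) in LWT males. In LWT females 0 rose, 17 fell and 4 were not called (0 and 19 over the list alone, camera adjusted p = 0.0136). The synthase Fasn fell by -3.31 ± 0.21 and -2.84 ± 0.21, the carboxylase Acaca by -1.83 ± 0.15 and -1.75 ± 0.15, and the lipogenic regulator Mid1ip1 by -2.75 ± 0.21 and -2.51 ± 0.21. Pnpla3 fell at least 23.5-fold in males and by -6.33 ± 0.55 in females, and its neighbour Pnpla5 fell by -5.09 ± 0.60 and -6.88 ± 0.60. For cholesterol synthesis and uptake, 0 rose, 18 fell and 6 were not called (0 and 20 over the list alone, camera adjusted p = 0.118 with an estimated correlation) in males. In females 1 rose, 15 fell and 8 were not called (1 and 17 over the list alone, camera adjusted p = 0.253 with an estimated correlation). The decarboxylase Mvd fell by -3.11 ± 0.31 and -2.24 ± 0.31. Fry and the preset correlation of 0.01 called the cholesterol list in both sexes, and the estimated correlation did not.

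Fasted LWT livers also raised the genes that make glucose. Of the gluconeogenic genes, 9 rose, 0 fell and 4 were not called (unchanged over the list alone, camera adjusted p = 0.00997) in males. In females 11 rose, 0 fell and 2 were not called (unchanged over the list alone, camera adjusted p = 0.0106). The glycerol kinase Gk rose by 1.05 ± 0.11 and 0.94 ± 0.11 and the transaminase Got1 by 1.84 ± 0.26 and 1.64 ± 0.26. The carboxykinase Pck1 rose by 1.95 ± 0.26 in males (adjusted p = 1.22e-07). Genes held down by insulin or raised by glucocorticoid moved with them: 11 rose, 0 fell and 4 were not called (12 and 0 over the list alone, camera adjusted p = 0.00683) in males. In females 11 rose, 1 fell and 3 were not called (unchanged over the list alone, camera adjusted p = 0.0521 with an estimated correlation). The metallothioneins Mt1 and Mt2 rose by 4.22 ± 0.42 and 5.34 ± 0.54 in males, and the growth factor binder Igfbp1 by 4.02 ± 0.44 and 2.42 ± 0.44. Amino acid breakdown followed in part: 13 rose, 0 fell and 8 were not called (14 and 0 over the list alone, camera adjusted p = 0.185 with an estimated correlation) in males. In females 16 rose, 1 fell and 4 were not called (18 and 2 over the list alone, camera adjusted p = 0.175 with an estimated correlation). Examples were Tdo2 (0.82 ± 0.13, adjusted p = 1.84e-06), which opens tryptophan breakdown, and Aass (1.02 ± 0.14, adjusted p = 3.08e-07), which opens lysine breakdown.

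Most endoplasmic reticulum chaperones fell, as did part of the cell cycle genes. Of the endoplasmic reticulum chaperones, 0 rose, 15 fell and 1 was not called (unchanged over the list alone, camera adjusted p = 0.0633 with an estimated correlation) in LWT males. In LWT females 1 rose, 13 fell and 2 were not called (unchanged over the list alone, camera adjusted p = 0.253 with an estimated correlation). The chaperone Hyou1 fell by -1.92 ± 0.22 and -1.54 ± 0.22, and the isomerase Pdia6 by -1.26 ± 0.15 and -1.22 ± 0.15. Of the cell cycle genes, 0 rose, 13 fell and 4 were not called (unchanged over the list alone, camera adjusted p = 0.167 with an estimated correlation) in males. In females 0 rose, 8 fell and 9 were not called (1 and 9 over the list alone, camera adjusted p = 0.413 with an estimated correlation). The replication licensing genes Mcm2 and Mcm5 fell by -1.62 ± 0.21 and -1.83 ± 0.34 in males and by -1.17 ± 0.21 and -2.18 ± 0.34 in females. Stellate cell and fibroblast markers fell in part: 0 rose, 6 fell and 8 were not called (0 and 7 over the list alone, camera adjusted p = 0.679) in males, led by Col3a1 (-1.21 ± 0.25, adjusted p = 0.000216).

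Smaller groups split under fasting. Among bile acid genes in LWT males, 1 rose, 2 fell and 12 were not called (unchanged over the list alone, camera adjusted p = 0.86, median 0.01, mean -0.06, test direction down), with the canalicular pump Abcb11 (-0.80 ± 0.12, adjusted p = 2.47e-06) down and the hydroxylase Cyp8b1 (1.14 ± 0.32, adjusted p = 0.00566) up. Of the clock genes in LWT males, 6 rose, 2 fell and 8 were not called (7 and 2 over the list alone, camera adjusted p = 0.679), and Per2 (-0.89 ± 0.25, adjusted p = 0.00553) fell while Ciart (1.79 ± 0.52, adjusted p = 0.00637) rose. Acute phase genes in LWT females showed 6 that rose, 1 that fell and 16 not called (unchanged over the list alone, camera adjusted p = 0.768, median -0.03, mean 0.30, test direction up), with the endotoxin binder Lbp (1.26 ± 0.15, adjusted p = 1.96e-08) and the antagonist Il1rn (2.67 ± 0.44, adjusted p = 5.03e-06) up. For xenobiotic metabolism in LWT males, 6 rose, 1 fell and 7 were not called (8 and 2 over the list alone, camera adjusted p = 0.345 with an estimated correlation), with Gadd45b (2.33 ± 0.29, adjusted p = 3.49e-08) and the reductase Por (1.22 ± 0.16, adjusted p = 5.36e-08) up. Hepatocyte markers were nearly still in LWT males, where 2 rose, 0 fell and 12 were not called (unchanged over the list alone, camera adjusted p = 0.7). The cholangiocyte markers in LWT males gave 1 that rose, 3 that fell and 4 not called (1 and 4 over the list alone, camera adjusted p = 0.497), with Krt23 (2.74 ± 0.48, adjusted p = 1.7e-05) up.

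In LKO livers, fasting still changed most genes of the lipid synthesis and glucose lists. With the estimated correlation camera called only 2 of 31 lists in males and 0 in females, where the preset correlation called 14 and fry 17. A list called in LWT but not in LKO livers is not a tested difference. For genotype by fasting camera called 3 of 31 lists in each sex, namely both oxidation lists and the other PPARα targets. Of the mitochondrial oxidation genes, 5 rose, 1 fell and 13 were not called (unchanged over the list alone, camera adjusted p = 0.806, median -0.02, mean 0.17, test direction up) in LKO males. In LKO females 7 rose, 5 fell and 7 were not called (unchanged over the list alone, camera adjusted p = 0.813). The genes that rose were led by the outer-membrane transferase Cpt1a (1.76 ± 0.12, adjusted p = 5.14e-15) and the long-chain dehydrogenase Acadl (0.95 ± 0.072, adjusted p = 1.48e-13) in males, and Cpt1a also rose in females (1.36 ± 0.12). In the peroxisomal list 4 rose, 7 fell and 4 were not called (5 and 7 over the list alone, camera adjusted p = 0.845) in males. In females 1 rose, 7 fell and 7 were not called (unchanged over the list alone, camera adjusted p = 0.581). Ehhadh fell by -1.14 ± 0.16 in LKO females (adjusted p = 2.29e-07). Among other PPARα targets, 9 rose, 2 fell and 10 were not called (10 and 2 over the list alone, camera adjusted p = 0.391) in males. In females 10 rose, 3 fell and 8 were not called (unchanged over the list alone, camera adjusted p = 0.256 with an estimated correlation). Fgf21 rose in both sexes (adjusted p = 5.85e-06 and 8.04e-09), with fasted means of -2.79 and -1.26, and no size is given because the fed means lie at background. Ketogenic genes gave 1 that rose, 2 that fell and 3 not called (unchanged over the list alone, camera adjusted p = 0.946) in males, omega-oxidation genes 5 rose, 1 fell and 3 were not called (unchanged over the list alone, camera adjusted p = 0.509) in males, and lipid droplet genes 7 rose, 3 fell and 5 were not called (unchanged over the list alone, camera adjusted p = 0.27 with an estimated correlation) in females.

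The fall of lipid synthesis in LKO livers was led by the master regulator Srebf1 (-3.64 ± 0.22 in males and -4.08 ± 0.22 in females) and Fasn (-3.16 ± 0.21 and -3.16 ± 0.21). Of that list, 2 rose, 18 fell and 1 was not called (unchanged over the list alone, camera adjusted p = 0.0856 with an estimated correlation) in LKO males. In LKO females 0 rose, 18 fell and 3 were not called (0 and 19 over the list alone, camera adjusted p = 0.116 with an estimated correlation). Glucose genes gave 9 that rose, 1 that fell and 3 not called (10 and 1 over the list alone, camera adjusted p = 0.0342) in males and 7 rose, 1 fell and 5 were not called (unchanged over the list alone, camera adjusted p = 0.256 with an estimated correlation) in females, with Pck1 up by 2.52 ± 0.26 and 2.08 ± 0.26. Insulin and glucocorticoid responsive genes gave 10 that rose, 0 that fell and 5 not called (12 and 0 over the list alone, camera adjusted p = 0.0342) in males, led by Mt1 (4.88 ± 0.42) and Igfbp1 (4.36 ± 0.44). In LKO females the bile acid synthase Cyp7a1 fell by -4.47 ± 0.47 and the nuclear receptor gene Nr4a1 rose by 4.38 ± 0.53 (adjusted p = 2.41e-10 and 7.4e-09). Genes of the amino acid response (Atf4) gave 10 that rose, 2 that fell and 7 not called (unchanged over the list alone, camera adjusted p = 0.256 with an estimated correlation) in LKO females, led by Trib3 (2.56 ± 0.23, adjusted p = 4.45e-12) and Gdf15 (3.51 ± 0.35, adjusted p = 1.12e-10). The chaperones gave 0 that rose, 15 that fell and 1 not called (unchanged over the list alone, camera adjusted p = 0.251 with an estimated correlation) in LKO males, and the cell cycle genes 0 rose, 14 fell and 3 were not called (0 and 15 over the list alone, camera adjusted p = 0.3 with an estimated correlation).

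Loss of Ppara in fed livers changed 327 genes in males (104 higher and 223 lower in LKO, 124 at least 2-fold) and 1112 in females (545 higher and 567 lower, 264 at least 2-fold). Both sexes shared 249 genes, all changed in the same direction (64 higher and 185 lower, with 2.663 and 5.941 expected of independent lists), and r across genes was 0.586. The female split rested on the scaling, with 51.0% of the calls lower, but 46.1% with quantile normalization, 43.0% with the uncorrected median signal, 42.9% with the deposited values and 47.2% with normexp. The female count depended on the slides, with 498 genes called without slide 2 and 616 without slide 6. Mitochondrial oxidation genes were lower before any fast: 0 were higher, 15 were lower and 4 were not called (0 and 16 over the list alone, camera adjusted p = 2.69e-07) in males. In females 0 were higher, 16 were lower and 3 were not called (0 and 18 over the list alone, camera adjusted p = 8.08e-07). The very-long-chain dehydrogenase Acadvl was lower by -1.02 ± 0.051 and -1.28 ± 0.051 (adjusted p = 1.01e-18 and 6.9e-23), and the isomerase Eci2 by -1.34 ± 0.082 and -1.58 ± 0.082. In the peroxisomal list 0 were higher, 9 were lower and 6 were not called (0 and 10 over the list alone, camera adjusted p = 0.000882) in males. For females 0 were higher, 9 were lower and 6 were not called (0 and 10 over the list alone, camera adjusted p = 0.000406). The multifunctional enzyme Hsd17b4 was lower by -0.86 ± 0.08 and -1.27 ± 0.08.

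The largest fed differences were in single target genes. The pantetheinase Vnn1 was lower by -5.12 ± 0.48 in males and -6.97 ± 0.48 in females (adjusted p = 1.49e-10 and 7.98e-15). Cyp4a10 and Cyp4a31 were lower by -3.49 ± 0.53 and -3.49 ± 0.50 in males and by -7.33 ± 0.53 and -6.90 ± 0.50 in females, where Cyp4a14 was at least 56.9-fold lower. The lysolipid transporter Mfsd2a was lower by -5.64 ± 0.38 in males, and the fat-partitioning gene Fitm1 at least 26-fold lower in females. Pdk4 went the other way, higher by 1.83 ± 0.32 in fed males (adjusted p = 0.000231) and by 1.97 ± 0.32 in fed females (adjusted p = 3.94e-05, a value chosen after it was seen). Of the omega-oxidation list, 0 were higher, 3 were lower and 6 were not called (0 and 5 over the list alone, camera adjusted p = 0.00545) in males. In females 0 were higher, 5 were lower and 4 were not called (1 and 5 over the list alone, camera adjusted p = 0.000302). Of the other targets, 1 was higher, 5 were lower and 15 were not called (2 and 8 over the list alone, camera adjusted p = 0.00545) in males. In females 1 was higher, 7 were lower and 13 were not called (2 and 7 over the list alone, camera adjusted p = 0.0121). Genes higher in LKO were led by Gldn, a junction protein gene of nerve (4.63 ± 0.73 and 4.95 ± 0.73), and Adam11 (2.75 ± 0.21 and 2.39 ± 0.21). The sulfotransferase Sult1e1 (4.21 ± 0.92, adjusted p = 0.00243) was higher in fed LKO females.

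More macrophage markers were called higher in fed LKO females than in fed LKO males. Of the Kupffer cell and macrophage list, 10 were higher, 0 were lower and 6 were not called (12 and 0 over the list alone, camera adjusted p = 0.0562 with an estimated correlation) in females, and 1 was higher, 0 were lower and 15 were not called (unchanged over the list alone, camera adjusted p = 0.453 with an estimated correlation) in males. The preset correlation of 0.01 called the female list, and the estimate did not. Markers included Mpeg1 (0.93 ± 0.16, adjusted p = 6.71e-05), Cd5l (0.78 ± 0.19, adjusted p = 0.00948) and Cd68 (0.71 ± 0.18, adjusted p = 0.0104). In the same comparison the neutrophil markers gave 0 higher, 0 lower and 9 not called (unchanged over the list alone, camera adjusted p = 0.649), the endothelial markers 1 higher, 0 lower and 11 not called (unchanged over the list alone, camera adjusted p = 0.553 with an estimated correlation), and the lymphocyte markers 0 higher, 0 lower and 11 not called (unchanged over the list alone, camera adjusted p = 0.634). Medians of several types were above 0: 0.762 for macrophages, 0.256 for endothelial cells, 0.259 for stellate cells and 0.248 for lymphocytes, on 6, 6, 5 and 5 of 6 slides. The sex by genotype test called 0 of the 16 macrophage markers in fed livers, so the sexes were not shown to differ in this shift (camera adjusted p = 0.302 with an estimated correlation).

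More genes were called between genotypes in fasted than in fed livers, and the difference in response itself is tested further below. In fasted males 3173 genes differed (1359 higher and 1814 lower in LKO, 525 at least 2-fold), and in fasted females 6119 (2373 higher and 3746 lower, 850 at least 2-fold). The male count was 1966 without slide 1 and 1750 with only the compared groups fitted. The highest count from other random splits of these male arrays was 2824. The direction of these counts rested on the scaling: lower genes were 57.2% of the male calls but 48.4% with quantile normalization, 48.9% with the uncorrected median signal and 70.0% with normexp background correction. They were 61.2% of the female calls but 47.0% with quantile normalization, 46.6% with the uncorrected median signal and 47.5% with the deposited values. The sexes shared 2189 genes changed in the same direction (771 higher and 1418 lower, with 151.5 and 319.3 expected of independent lists), and 5 changed in opposite directions (r across genes 0.729).

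Nearly every gene of the mitochondrial and peroxisomal oxidation lists was lower in fasted LKO livers. In the mitochondrial list 0 were higher, 18 were lower and 1 was not called (unchanged over the list alone, camera adjusted p = 2e-06) in males. In females 0 were higher, 19 were lower and 0 were not called (unchanged over the list alone, camera adjusted p = 2.24e-05). Acadvl was lower by -1.44 ± 0.051 and -1.71 ± 0.051 (adjusted p = 1.39e-24 and 1.14e-27), and the inner-membrane transferase Cpt2 by -1.72 ± 0.078 and -1.94 ± 0.078. In the peroxisomal list 0 were higher, 14 were lower and 1 was not called (unchanged over the list alone, camera adjusted p = 3.03e-06) in males. For females 0 were higher, 15 were lower and 0 were not called (unchanged over the list alone, camera adjusted p = 3.16e-05). Hsd17b4 was lower by -1.57 ± 0.08 and -2.06 ± 0.08, and the thiolase Acaa1b by -2.41 ± 0.14 and -3.29 ± 0.14. Ketogenic genes gave 0 higher, 3 lower and 3 not called (0 and 5 over the list alone, camera adjusted p = 0.0251) in males. In females 1 was higher, 4 were lower and 1 was not called (unchanged over the list alone, camera adjusted p = 0.121 with an estimated correlation). Omega-oxidation genes gave 1 higher, 5 lower and 3 not called (unchanged over the list alone, camera adjusted p = 0.0251) in males. In females 0 were higher, 8 were lower and 1 was not called (unchanged over the list alone, camera adjusted p = 0.00467). Other targets gave 0 higher, 12 lower and 9 not called (0 and 13 over the list alone, camera adjusted p = 0.000142) in males. For females 0 were higher, 15 were lower and 6 were not called (unchanged over the list alone, camera adjusted p = 6.38e-05). Retsat was lower by -2.58 ± 0.16 and -4.39 ± 0.16, and Vnn1 by -6.92 ± 0.48 and -7.21 ± 0.48.

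Among droplet genes in fasted livers, 1 was higher, 8 were lower and 6 were not called (2 and 10 over the list alone, camera adjusted p = 0.0335) in males. In females 2 were higher, 11 were lower and 2 were not called (unchanged over the list alone, camera adjusted p = 0.0575 with an estimated correlation). Fitm2 was lower by -1.69 ± 0.12 and -1.85 ± 0.12, Fitm1 by -3.19 ± 0.48 in males and at least 31.1-fold in females, while the coat gene Plin3 (1.13 ± 0.11, adjusted p = 3.76e-11) was higher in females. Genes outside fat oxidation moved as well. The orphan receptor gene Esrrg was at least 7.82-fold lower in males and at least 23.9-fold lower in females, and the repair gene Rad51b (-5.31 ± 0.27, adjusted p = 7.58e-20) was lower in females. The serine carrier gene Serinc2 (-5.01 ± 0.26, adjusted p = 2.18e-19) and the melatonin receptor gene Mtnr1a (-5.14 ± 0.36, adjusted p = 6e-15) were lower in males. Gldn stayed higher (4.76 ± 0.73 and 5.42 ± 0.73), and the lipoprotein gene Apoa4 (2.25 ± 0.26, adjusted p = 1.24e-08) was higher in males. The thioredoxin inhibitor gene Txnip was lower by -1.43 ± 0.20 and -2.06 ± 0.20.

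Most cholesterol genes were higher in fasted LKO males. In males 17 were higher, 0 were lower and 7 were not called (unchanged over the list alone, camera adjusted p = 0.304 with an estimated correlation), and in females 4 were higher, 5 were lower and 15 were not called (6 and 5 over the list alone, camera adjusted p = 0.945). The sexes were not shown to differ in this list (sex by genotype, camera adjusted p = 0.425 with an estimated correlation). The epoxidase Sqle was higher by 1.91 ± 0.22 and 0.90 ± 0.22 (adjusted p = 8.06e-09 and 0.00154). Part of both stress response lists was higher in fasted LKO females. Of the antioxidant (Nrf2) genes there, 7 were higher, 0 were lower and 6 were not called (unchanged over the list alone, camera adjusted p = 0.158 with an estimated correlation), with the heme oxygenase Hmox1 (1.86 ± 0.21, adjusted p = 1.39e-09) and the ligase subunit Gclc (0.62 ± 0.12, adjusted p = 7.68e-05). Of the amino acid response (Atf4) genes there, 8 were higher, 1 was lower and 10 were not called (unchanged over the list alone, camera adjusted p = 0.171 with an estimated correlation), with Trib3 (1.75 ± 0.23, adjusted p = 5.88e-08) and Atf3 (2.22 ± 0.35, adjusted p = 2.8e-06). Macrophage markers gave 6 higher, 0 lower and 10 not called (10 and 0 over the list alone, camera adjusted p = 0.544 with an estimated correlation) in fasted females, and 0 were higher, 0 were lower and 16 were not called (5 and 0 over the list alone, camera adjusted p = 0.634 with an estimated correlation) in fasted males. Xenobiotic metabolism genes gave 2 higher, 5 lower and 7 not called (3 and 5 over the list alone, camera adjusted p = 0.945) in fasted females, with the first gene of heme synthesis, Alas1 (-1.30 ± 0.26, adjusted p = 0.000125), lower.

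The response to fasting differed between genotypes for 326 genes in males (62 with a more positive and 264 with a more negative response in LKO) and for 1880 in females (615 and 1265). Lower values made up 67.3% of the female calls, but 52.1% with quantile normalization and 51.7% with the uncorrected median signal. The male count was 164 without slide 1 and 192 without slide 3, and the female count 1189 without slide 6. Oxidation genes led both sexes: 0 had a more positive response, 15 a more negative one and 4 were not called (1 and 17 over the list alone, camera adjusted p = 0.000141) in males for the mitochondrial list. In females 0 had a more positive response, 17 a more negative one and 2 were not called (unchanged over the list alone, camera adjusted p = 0.0014). For the peroxisomal list the result was camera adjusted p = 1.74e-05 in males and camera adjusted p = 0.00028 in females, and for the other targets camera adjusted p = 0.0054 and camera adjusted p = 0.0014. The response of Ehhadh was more negative in LKO by -2.88 ± 0.23 and -2.96 ± 0.23, that of Retsat by -1.90 ± 0.22 and -1.97 ± 0.22, and that of Pdk4 by -2.71 ± 0.46 and -3.73 ± 0.46 (adjusted p = 0.000291 and 3.54e-07). The lipase inhibitor G0s2 had a response more negative by -2.35 ± 0.59 and -4.36 ± 0.59, going from 3.14 to 5.77 in LWT females and from 3.88 to 2.14 in LKO females. In females the chemokine Cxcl1 (2.86 ± 0.56, adjusted p = 0.000539) had a more positive response in LKO.

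**Figure D4:**
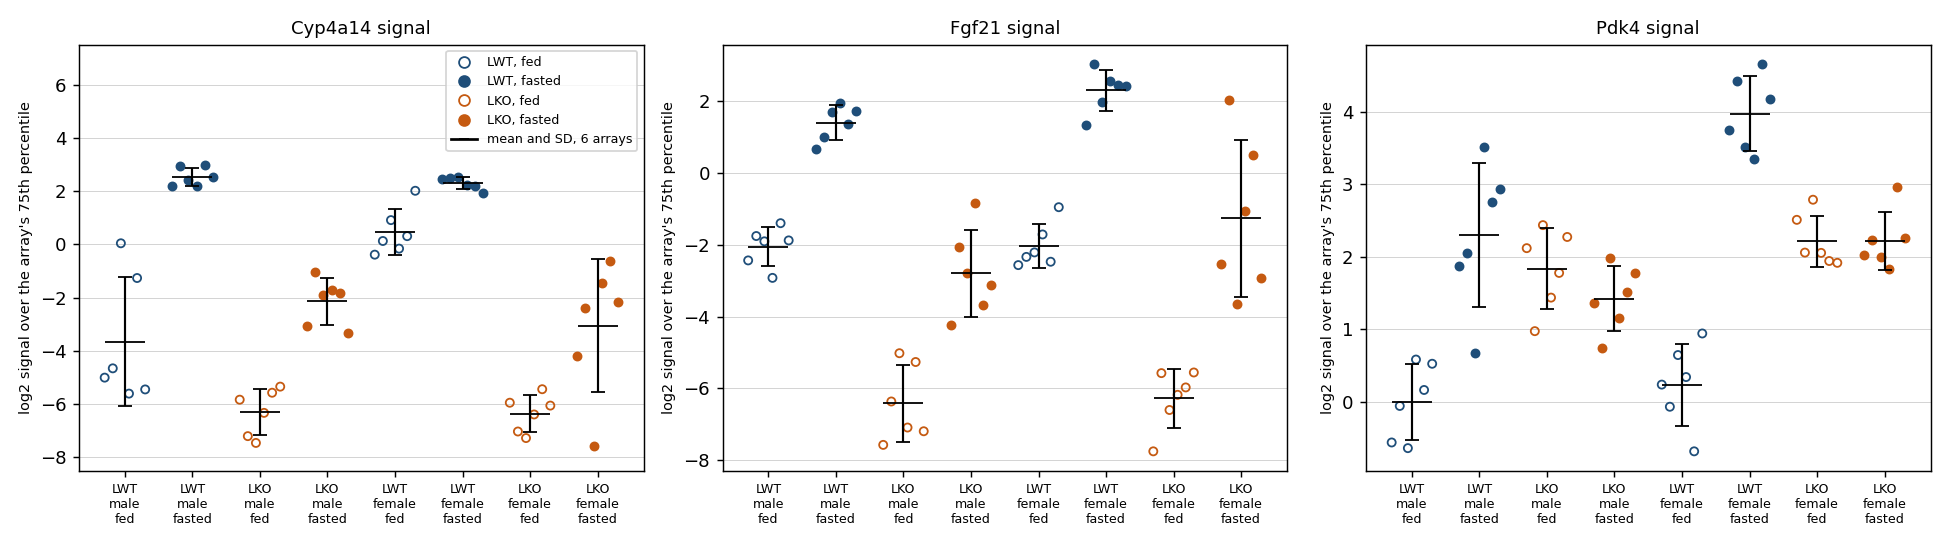
Log2 signal of Cyp4a14, Fgf21 and Pdk4 on each array (points) in the 8 groups, 6 arrays per group. The vertical axis is in log2 units relative to the array's 75th percentile. Pdk4 goes from 0.24 to 3.97 with fasting in LWT females and stays at 2.21 and 2.22 in LKO females.

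Genes raised by fasting in LWT were often lower in fasted LKO. In males 645 of 3255 raised genes (19.8%) were lower in fasted LKO, and in females 1131 of 3707 (30.5%). Both comparisons use the same fasted LWT arrays, which alone makes an overlap possible. Independent lists of these sizes would share 277.4 and 652.5 genes. With the 6 fasted LWT arrays split so that each comparison used 3 of them, the overlaps were 425 and 403 in males (147.6 and 149 expected) and 775 and 699 in females (299.9 and 487.2 expected). The covariance of both effects across genes was -0.0469 in males and -0.0671 in females, against -0.019 and -0.0185 simulated from shared arrays. The correlation was weaker than simulated, at -0.235 and -0.273 against -0.494 and -0.486. The simulated groups held no real effects, so the simulated correlation rests on the shared arrays alone. With the fasted LWT arrays split as above, r was -0.122 and -0.115 in males and -0.31 and -0.07 in females. The simulation drew on the residuals of all 48 arrays, and the fasted LWT males had the lowest mean correlation within a group (0.9882). For males the simulated covariance may therefore understate what shared arrays alone give. Of the overlapping genes, 177 and 499 also had a called difference in response, and 178 and 316 still rose with fasting in LKO. Acadm and Ehhadh were in both sexes' overlap (LKO effect -0.73 ± 0.075 and -2.96 ± 0.16 in fasted males, -1.09 ± 0.075 and -3.06 ± 0.16 in fasted females).

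Male and female livers differed in 5205 genes when LWT and fed (2276 higher and 2929 lower in females), 5405 when LWT and fasted (2384 and 3021), 6811 when LKO and fed (2992 and 3819) and 7397 when LKO and fasted (2843 and 4554). The count for fasted LWT livers was 10969 without the filter and 3357 with only the compared groups fitted. Which direction held more genes rested on the scaling in all but the fasted LKO livers. Lower genes made up 56.3% of the calls in fed LWT livers, 55.9% in fasted LWT livers, 56.1% in fed LKO livers and 61.6% in fasted LKO livers. With the uncorrected median signal these shares were 47.6%, 48.1%, 46.1% and 50.2%, with quantile normalization 49.8%, 50.5%, 46.7% and 51.1%, and with normexp 62.8%, 73.4%, 60.8% and 64.3%. The sex differences of LWT and LKO livers correlated at r = 0.886 when fed and 0.842 when fasted. Known female-biased genes were higher in females: 25 were higher, 0 were lower and 3 were not called (unchanged over the list alone, camera adjusted p = 1.18e-08) in fed LWT livers, and 26 were higher, 0 were lower and 2 were not called (27 and 0 over the list alone, camera adjusted p = 2.43e-08) in fed LKO livers. Fasted livers gave 27 higher, 0 lower and 1 not called (28 and 0 over the list alone, camera adjusted p = 1.5e-08) for LWT, and 25 were higher, 0 were lower and 3 were not called (26 and 0 over the list alone, camera adjusted p = 6.37e-07) for LKO. Known male-biased genes were lower in females, where 0 were higher, 21 were lower and 3 were not called (unchanged over the list alone, camera adjusted p = 0.000119) in fed LWT livers, and 0 were higher, 23 were lower and 1 was not called (unchanged over the list alone, camera adjusted p = 0.000377) in fed LKO livers. Fasted livers gave 0 higher, 24 lower and 0 not called (unchanged over the list alone, camera adjusted p = 1.65e-05) for LWT, and 0 were higher, 24 were lower and 0 were not called (unchanged over the list alone, camera adjusted p = 0.000179) for LKO.

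Large sex differences were seen in cytochrome and sulfotransferase genes. In fed LWT livers the cytochrome Cyp2b13 was at least 1750-fold higher in females, and the sulfotransferases Sult2a2 and Sult3a1 at least 772-fold and at least 743-fold higher (adjusted p = 1.19e-33, 1.31e-19 and 6.6e-22). In fed LKO livers Cyp2b13 was at least 1110-fold higher. The male omega-hydroxylase Cyp4a12a was lower in females by -10.82 ± 0.41, -9.84 ± 0.41, -10.76 ± 0.41 and -10.89 ± 0.41 in fed LWT, fasted LWT, fed LKO and fasted LKO livers, and the testosterone hydroxylase Cyp2d9 by -3.92 ± 0.16, -4.45 ± 0.16, -4.04 ± 0.16 and -4.24 ± 0.16. Cux2, a repressor of male genes under growth hormone, was higher by 6.12 ± 0.41 in fed LWT and 4.82 ± 0.41 in fasted LKO females. The asparagine synthetase Asns (-4.49 ± 0.71, adjusted p = 6.01e-06) and the bile acid hydroxylase Cyp7b1 (-3.29 ± 0.30, adjusted p = 2.31e-11) were lower in fed LWT females, and the drug-inducible Cyp2b10 (6.10 ± 0.60, adjusted p = 1.73e-10) higher. Of the growth hormone axis in fed LWT livers, 5 were higher, 1 was lower and 7 were not called (5 and 3 over the list alone, camera adjusted p = 0.0716 with an estimated correlation).

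Markers of some other cells differed between the sexes as well, and the dimmer male arrays were not tested as a source. Of the macrophage markers, 13 were higher, 0 were lower and 3 were not called (15 and 0 over the list alone, camera adjusted p = 0.168 with an estimated correlation) in fasted LWT females. Lymphocyte markers gave 9 higher, 1 lower and 1 not called (unchanged over the list alone, camera adjusted p = 0.158 with an estimated correlation) in fed LKO livers, led by Nkg7 (1.30 ± 0.19, adjusted p = 1.29e-06), and endothelial markers 10 higher, 0 lower and 2 not called (unchanged over the list alone, camera adjusted p = 0.195 with an estimated correlation). Neutrophil markers gave 5 higher, 0 lower and 4 not called (6 and 0 over the list alone, camera adjusted p = 0.214 with an estimated correlation) in fasted LWT livers. In fed LWT livers 1 macrophage, 6 lymphocyte, 2 endothelial and 1 neutrophil markers were higher in females, and in fasted LKO livers 14, 6, 6 and 4. Endothelial markers gave 1 in fasted LWT livers, and neutrophil markers 1 in fed LKO livers. Blood and neighbouring tissue markers gave 0 higher, 4 lower and 6 not called (0 and 6 over the list alone, camera adjusted p = 0.0716 with an estimated correlation) in fed LWT livers, with the red cell gene of heme synthesis, Alas2 (-3.14 ± 0.13, adjusted p = 4.99e-23), lower. Hepatocyte markers gave 0 higher, 10 lower and 4 not called (0 and 12 over the list alone, camera adjusted p = 0.361 with an estimated correlation) in fasted LWT livers. Sex chromosome genes gave 4 higher, 4 lower and 1 not called (unchanged over the list alone, camera adjusted p = 0.011) in fed LWT livers. That list holds X-linked and Y-linked genes, whose sex differences run in opposite directions. Camera tests a common direction, so its p-value shows no joint shift of these genes. Chaperones were lower in fed LKO females, where 0 were higher, 14 were lower and 2 were not called (0 and 15 over the list alone, camera adjusted p = 0.29 with an estimated correlation), with Hyou1 (-1.01 ± 0.22, adjusted p = 0.000321) and Calr (-0.78 ± 0.18, adjusted p = 0.000619).

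Few genes responded to fasting differently in LWT males and females: 83 were called, 46 with a more positive and 37 with a more negative response in females (44.6% more negative, but 51.6% with the deposited values). The count was 29, 52, 20, 37 and 10 without slides 1, 2, 4, 5 and 6, and 136 without replicate 5 of the fasted LWT males, and other processing at the same threshold gave from 32 (no filter) to 158 (normexp). Rcan1, a calcineurin inhibitor gene, had a more positive response in females (1.47 ± 0.24, adjusted p = 0.00136), while the transporter Slco1a1 (-2.74 ± 0.50, adjusted p = 0.00364) fell more. Droplet genes rose more in females as a list: 2 rose more, 0 rose less and 13 were not called (8 and 0 over the list alone, camera adjusted p = 0.0194), with Cidec (2.37 ± 0.52, adjusted p = 0.0272) and Plin4 (1.94 ± 0.47, adjusted p = 0.0485). Other PPARα targets gave 0 rose more, 0 rose less and 21 were not called (3 and 0 over the list alone, camera adjusted p = 0.0489), and the growth hormone axis 0 rose more, 0 rose less and 13 were not called (1 and 4 over the list alone, camera adjusted p = 0.0194). In both of these lists limma called 0 genes over all genes tested.

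The loss of Ppara acted differently in the sexes for 15 genes when fed (6 more positive and 9 more negative in females) and 256 when fasted (87 and 169). The fed count was 9 without slide 4 and 27 with the deposited values. The fasted count was 109, 27, 111, 128 and 100 without slides 1, 3, 4, 5 and 6, and other processing at the same threshold gave from 37 (only the compared groups) to 432 (normexp). Lower values made up 66.0% of the fasted calls, but 50.2% with quantile normalization, 53.2% with normexp, 48.2% with the uncorrected median signal and 44.5% with the deposited values, and 9 of the 15 fed calls but 37.0% with the deposited values. Retsat was lowered more in females in both states (-1.74 ± 0.22 fed and -1.81 ± 0.22 fasted, adjusted p = 5.48e-06 and 4.27e-06), as was Rad51b (-3.12 ± 0.38 and -2.62 ± 0.38). The solute carrier gene Slc35f2 was at least 5.08-fold lower in fed LKO males. The glutaminyl cyclase Qpct (-1.16 ± 0.15, adjusted p = 5.48e-06) was lowered more in fed females. In fasted females Trib3 was raised more (1.57 ± 0.32, adjusted p = 0.00816), as was Hmox1 (adjusted p = 0.0199). Omega-oxidation genes in fed livers gave 0 lowered less, 2 lowered more and 7 not called (0 and 3 over the list alone, camera adjusted p = 0.0358), with Cyp4a10 (-3.83 ± 0.75, adjusted p = 0.0153). A larger loss was not told apart from a higher level in fed LWT females. In this list Cyp4a14 lay at -0.39 to 2.01 there, but at -5.60 to 0.04 in fed LWT males and -7.46 to -5.34 in fed LKO males. The joint test of sex, genotype and fasting called 0 genes with limma (1172 at unadjusted p under 0.05, smallest adjusted p = 0.14).

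Checks of these comparisons used the slides and simulated data. Every slide held 1 array of each group, so blocking on slide left the estimates of complete genes unchanged. On simulated data with 2-fold changes the test recovered 78 to 96% of changed genes for pairs of groups, 64 to 80% for differences in response and 46% for the joint test, with 4 to 11 false calls among 21282 genes. Those data held no correlation between genes, no slide effects and few changed genes, so these rates do not describe the real fits. List calls are those of camera with the correlation estimated from the data, which kept 55 of the 209 calls made with the preset correlation.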

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

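The tests of the difference between the sexes in Ppara, of the hepatocyte share, of the Ppara signal left in LKO livers and of both relations within each sex were chosen only after the results were seen. Of 64 groups of 6 arrays examined, 7 held an array far from the other 5, where chance gives about 1 in 20 groups, or 3.2 of these 64. Xist stood apart at -5.69 on replicate 5 of the fed LWT males, -3.33 on replicate 6 of the fed LKO males, -5.30 on replicate 6 of the fasted LKO males and -1.04 on replicate 1 of the fasted LKO females. The other 5 fed LKO males lay between -7.58 and -7.20, so their replicate 6 held a raised Xist signal, and no explanation for it was tested. The dimmer Ppara probe stood apart at 4.03 on replicate 3 of the fed LWT males. The percent of probes well above background stood apart at 43.15 on replicate 5 of the fed LWT males and at 59.85 on replicate 3 of the fasted LKO males.

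Tests of the difference between groups of animals singled out 326 genes for genotype by fasting in males, 1880 in females, 83 for sex by fasting in LWT, and 15 and 256 for sex by genotype in fed and fasted livers. The largest fitted differences in the fasting response of LWT females against males were Adra2a (3.83), Cidec (2.37) and Mmp7 (2.06), and Prok1 (-3.52), Cym (-3.10) and Dio3os (-2.98). For sex by genotype in fed livers they were Slc35f2 (3.77), Mfsd2a (3.03) and Susd4 (1.84), and Fitm1 (-4.76), Cyp4a10 (-3.83) and Cyp4a31 (-3.41). In fasted livers they were Slc35f2 (2.87), H2al3 (2.44) and Hrk (2.27), and Moxd1 (-5.41), Fitm1 (-3.14) and Tmeff2 (-3.11). Adra2a, Cym, Slc35f2, Fitm1, H2al3, Moxd1 and Tmeff2 were well above background on no array of at least 1 group compared, so their fitted values are no measured sizes, and their place among the largest rests on dim signal.

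More genes were called between genotypes in fasted females (6119) than in fasted males (3173). Dimmer arrays and a wider spread in the fasted LWT males were argued against: with each comparison's own error taken off, the SD of the fold changes over 16143 genes bright on all arrays was 0.392 in females and 0.302 in males. The ratio was 1.3, and 1.23 to 1.39 with a slide left out. A larger loss of Ppara signal in females stays open, with a difference of -0.51 (SE 0.149) whose adjusted p from limma over all genes was 0.0691 (0.00132 unadjusted). It was below 0 on 6 of 6 slides, and sex itself also stays open, as untested.

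Most macrophage markers were called higher in fed LKO females, but camera with the estimated correlation did not call the list. A lower share of hepatocyte RNA was argued against as the whole source, since it would raise the markers of all other cell types alike, but the macrophage median (0.762) exceeded that of the lymphocyte, endothelial, stellate and cholangiocyte markers (0.189) by 0.573, and by 0.115 to 0.883 on 6 of 6 slides. It could supply part of the shift, as the endothelial (0.256), stellate (0.259) and lymphocyte (0.248) medians were above 0 on 5 or 6 of 6 slides and the cholangiocyte median was 0.032. The slide of the array was argued against by the design. Each slide held 1 array of every group, so a shift common to a slide cancels in these differences. The macrophage median was above 0 on 6 of 6 slides (0.267 to 1.313), so no single slide carried the shift. More macrophages, or more RNA from each, may explain the shift, and the arrays do not separate these readings.

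Fasting raised some PPARα targets in LKO livers too: of 85 genes on 6 lists, 59 rose in LWT livers of both sexes, and 16 of these also rose in LKO livers of both sexes. Ppara signal left in LKO livers stays open as the source: over the 12 fasted LKO arrays the mean of the 16 genes fell as Ppara rose (r = -0.787, permutation p = 0.0129, adjusted over 2 relations 0.0129, r = -0.619 without the 2 farthest arrays), but females carried this (r = -0.917, exact permutation p = 0.0111) and males did not show it (r = -0.159, p = 0.789). That signal may also come from outside the deleted part or from other cells, so it does not measure working receptor. The mean of the 16 genes took unscaled log2 values and included Fgf21, which ran from -3.64 to 2.05 in fasted LKO females. The mean therefore weighs the most variable genes most and does not show that the 16 genes moved together. Another regulator engaged by fasting is a candidate explanation for Fgf21, which followed the mean of the Atf4 list (r = 0.801, permutation p = 0.00544, adjusted 0.0109), again mainly in females (r = 0.968, exact permutation p = 0.00278, against 0.477 and 0.342 in males, and 0.822 without the 2 farthest arrays). Fgf21 is not on that list, and the other 15 genes were not tested for it.

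For pairs of groups the arrays were regrouped at random, and for differences between effects the residuals of a fit without that difference were moved among the arrays, which kept the other effects in place. Among these 100 splits, the real one included, no other gave as many genes, except for the joint test of sex, genotype and fasting. Apart from the overlaps, this argued against a random grouping of the arrays, and 1 in 100 is the lowest share that 100 splits can show. For fasting the real and the highest other counts were 6404 and 3051 (LWT males), 7017 and 3719 (LWT females), 7818 and 4517 (LKO males) and 8830 and 6405 (LKO females). For genotype they were 327 and 95 in fed males, 1112 and 277 in fed females, 3173 and 2824 in fasted males and 6119 and 4103 in fasted females. For sex they were 5205 and 1508 (LWT fed), 5405 and 2998 (LWT fasted), 6811 and 3738 (LKO fed) and 7397 and 3659 (LKO fasted). Differences between effects gave 326 and 4, 1880 and 15 for genotype by fasting in males and females, 83 and 1 for sex by fasting, and 15 and 1, 256 and 53 for sex by genotype in fed and fasted livers. Genes raised by fasting and lower in fasted LKO numbered 645 and 428 in males, and 1131 and 56 in females. The joint test gave 0 genes in all 100 splits, so chance is not excluded there.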

How the results depend on the processing

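All alternatives were chosen before the data were examined, except the 4 single arrays left out in turn, which were chosen after seeing the data for technical reasons. Fits without other sets of arrays were also tried after seeing the data and are not reported, since the arrays had been picked by an outcome measured in them. Ppara was lower in LKO livers in all 4 pairs under every alternative run for it, which leaves out the single arrays and the other thresholds, by -0.75 to -0.62 in fed males and -1.58 to -1.46 in fasted females with a slide left out. Quantile normalization, slide or wash batch as a block, the mean of a gene's probes and the filter on all 48 arrays moved no count by over 1.5 times, nor did any alternative run for the overlap of genes raised by fasting and lower in fasted LKO (502 to 616 in males and 880 to 1059 in females with a slide left out).

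A 2-fold minimum, which tests a narrower set by its construction, left 995 and 965 genes for fasting in LWT males and females, 1217 and 1339 in LKO males and females, 124 and 264 for genotype in fed males and females, 525 and 850 in fasted ones, 105 and 326 for genotype by fasting in males and females, 714, 861, 961 and 978 for sex in LWT fed, LWT fasted, LKO fed and LKO fasted livers, 38 for sex by fasting and 65 for sex by genotype when fasted. Adjusted p under 0.01 left 510 and 1764 for genotype in fed females and fasted males, 162 and 965 for genotype by fasting, 3050, 3082 and 4499 for sex in LWT fed, LWT fasted and LKO fed livers, 19 for sex by fasting, and 9 and 52 for sex by genotype. A fit of only the groups compared, with fewer arrays, gave 1750 for genotype in fasted males, 3357 for sex in fasted LWT livers, 44 for sex by fasting and 37 for sex by genotype when fasted. No filter gave 10969, 32 and 112 for the last 3 of these. Normexp gave 158 for sex by fasting and 432 for sex by genotype when fasted, the deposited values 126 for sex by fasting and 27 for sex by genotype when fed, and the median signal 1 gene for the joint test of sex, genotype and fasting. Beyond fewer arrays and stricter thresholds, the cause was not tested.

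With a slide or an array left out, counts ran from 498 to 1064 for genotype in fed females (498 without slide 2, 616 without slide 6), 1966 to 3099 in fasted males (1966 without slide 1), 164 to 362 for genotype by fasting in males (164 without slide 1, 192 without slide 3) and 1189 to 2140 in females (1189 without slide 6). Sex by fasting ran from 10 to 136, with 29, 52, 20, 37 and 10 without slides 1, 2, 4, 5 and 6, and 136 without replicate 5 of the fasted LWT males. Sex by genotype ran from 9 to 15 when fed (9 without slide 4) and 27 to 337 when fasted (109, 27, 111, 128 and 100 without slides 1, 3, 4, 5 and 6). The joint test gave 0 to 1, with 1 gene without slide 2 and without slide 5. The other counts stayed within 1.5 times.

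Some named genes reversed in sign with no call. Ambp and Rbp4 became 0.003 for genotype in fasted males with quantile normalization and with the median signal. Ambp became 0.018 and 0.043 for sex in fed LKO livers under these, and for sex in fasted LWT livers Acaa2 became 0.101 and 0.122, Rbp4 0.039 and 0.017, and Mpo -0.099 with normexp. The cause was not tested. Of the other named values 57 lost their call with quantile normalization, 80 with the median signal, 55 with normexp and 100 without the filter. Fry called 135 and the preset correlation 154 list results that the estimated correlation did not, and neither lost one. The 135 of fry can include lists for which fry gave the other direction, and these were not counted apart.

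The labels tie nothing to the replicate number: over 168 pairs of the same number the deviations from group means correlated at -0.235 to 0.321 (mean 0.012), 34 pairs were over 0.1, and 17 of 48 arrays matched their own number best, where chance gives about 8, a hint from the data and not from the design. Arrays of the same slide had 47 of 168 pairs over 0.1 (mean 0.04), and of the same wash batch 79 of 280 (mean 0.039). With the replicate block sex by fasting gave 127 genes, and the other counts stayed within 1.5 times. A component holding 7.15% of the variance within groups followed the slides (r² = 0.728). Dim probes limit all folds, since 43.15 to 60.93% of probes were well above background.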

Other observations

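Genes outside the lists separated the genotypes too, and no explanation was tested for those below. The endosomal gene Rufy4 and the calcium sensor gene Caln1 were lower in LKO livers, by -4.83 ± 0.35 and -4.69 ± 0.43 in fasted males. The inhibitor Serpinb1a was higher in fed LKO livers of males and females (2.44 ± 0.40 and 2.72 ± 0.40), and the acetyltransferase relative Nat8f6 in fasted LKO females (3.58 ± 0.37). The Wnt inhibitor Wif1 was at least 2.07-fold higher in fed LKO males and at least 2.83-fold higher in fasted LKO females. The chemokine Ccl7 was at least 4.49-fold higher in fasted LKO females. The repressor gene Zfp536 had a more negative response to fasting in LKO males and females (-2.49 ± 0.38 and -3.91 ± 0.38), and the vesicle gene Rab30 in males (-2.97 ± 0.35).

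Single genes outside the lists changed with fasting, and groups of such genes were not tested. The glycogen-targeting subunit Ppp1r3g rose by 5.21 ± 0.91 in LWT males, 6.12 ± 0.91 in LKO males and 5.02 ± 0.91 in LKO females, and the lipid kinase Pip5k1a by 4.56 ± 0.50 in LWT males and 3.62 ± 0.50 in LWT females. The kinase Ptk6 fell by -4.06 ± 0.35, -3.49 ± 0.35 and -4.24 ± 0.35 in LWT females, LKO males and LKO females, and the fatty acid binder Fabp5 by -3.46 ± 0.39 and -4.85 ± 0.39 in LKO males and females. Cdkn1a, which halts the cell cycle, rose by 3.53 ± 0.52 in LWT females. Among sex differences of genes that are on the lists, the fatty acid elongase Elovl3 was lower in LKO females by -6.94 ± 0.67 when fed and -8.25 ± 0.67 when fasted. The steroid enzyme Hsd3b5, also on a list, was lower by -5.77 ± 0.68 and -8.53 ± 0.68 in fed and fasted LWT females.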
